A study of Arabidopsis thaliana with 8 samples.

How the data were processed

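RNA-seq and ribosome footprint libraries of mock and elf18-treated leaves were taken from the deposited tables, with no reads processed here. The deposited values were raw read counts per gene in 2 tables, one over exons for the 4 RNA libraries and one over coding sequences for all 8 libraries; the authors did not normalise these counts, as the values are whole numbers whose totals differ between libraries. Per the submitters' processing notes the tools were CASAVA 1.8.2, Bowtie2 2.0 and HTSeq (version not given in the sources used here) with genome build TAIR10. Trimming, removal of ribosomal reads, footprint length limits, strand setting and the handling of multiply matching reads were not given in the sources used here. Each table held 27172 genes. Footprint values were blank for 62 genes, 51 of them with RNA exon counts, and these genes were kept out of every coding-sequence test. In 66 genes the coding-sequence count exceeded the exon count in a library. No gene encoded in a plastid or mitochondrion was in the tables.

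Gene symbols came from the supplied locus table, which was used for names only: 26685 loci had an entry and 487 had none. No coordinates are printed. No reference sequence of the build came with the series, so GC content and gene length were not checked.

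Samples fell into 4 groups of 2: mock RNA, elf18 RNA, mock footprints and elf18 footprints. RNA and footprint libraries were matched to lysates by the sample ID numbers, since per the labels' protocols part of each lysate went to RNA and part to footprints. The lysates carried the numbers 2 and 3 in mock and 1 and 3 with elf18, and nothing in the labels says that a number marks a batch or day shared by mock and elf18, so replicate numbers were not taken to pair mock with elf18. As a check, the deviations of same-lysate libraries from their group means were correlated across 10969 genes, and gave r = -0.0288 in mock and -0.0178 with elf18.

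All calls, tests and lists named below, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. For each comparison, edgeR's TMM normalization, filterByExpr with a minimum of 10 counts, glmQLFit and glmQLFTest were used, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The RNA comparison was fitted on exon counts and again on coding-sequence counts, and the footprint comparison on coding-sequence counts, each with treatment alone and 2 residual degrees of freedom. Translational efficiency was the interaction of assay and treatment over all 8 coding-sequence libraries, with 4 residual degrees of freedom; this fit treats the RNA and footprint libraries of a lysate as independent, and a fit with the lysate as a block was run beside it. The ratio of footprints to RNA in mock was a contrast of the same fit. An exact permutation of 2 against 2 libraries cannot give a p under 0.333, so none was used.

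The 18 gene lists, of 332 members of which 331 were in the tables, were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists within a comparison. With an estimated correlation, camera takes its p from the residual degrees of freedom of the fit, 2 or 4 here, so few lists can pass. A list of ribosomal proteins by description was planned and not made, because the locus table described only 7 genes in that way, and lists of plastid and mitochondrial genes had no members. Changes in RNA and footprints were correlated across genes. Efficiency was correlated with RNA changes both within the same libraries and between libraries that share none.

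Genes were named by rule. EFR, FRK1, TBF1 and WRKY33 were always named. Up to 8 rising and 8 falling genes per comparison followed, those with the largest log2 fold change among called genes with a mean of at least 10 CPM (counts scaled to library size) and no overlap between the groups. Up to 3 called members of each list were added, and where fewer than 4 genes passed in a direction, the genes with the largest test statistic filled up to 4 as values. Further list members, genes called only under an alternative and genes of the mock ratio were named after their values were seen.

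Where a group had 0 counts the fitted fold was replaced by a lower bound from a floor of 3 counts over the group, and where it had 1 to 3 counts by the ratio of counts with a 95% exact binomial interval. Depth set these limits: 3 counts correspond to 0.234 to 0.468 CPM in the RNA libraries and 0.447 to 0.631 in the footprint libraries on coding sequences. The chi-square between replicates per degree of freedom was 13.2 for mock RNA, 63.9 for elf18 RNA, 33.5 for mock footprints and 24.3 for elf18 footprints, so spread beyond counting limited the precision. No molecular identifiers are mentioned in the labels.

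Each comparison was tested on simulated data, with counts drawn for the real genes at the real depths and 200 genes changed. Of 100 genes changed 4-fold, 58 were recovered for RNA on exons, 41 for RNA on coding sequences, 33 for footprints and 24 for efficiency; of 100 changed 2-fold, 5, 3, 4 and 3 were recovered. Of unchanged genes 15, 9, 5 and 9 were called. In each comparison these made up a larger share of the simulated calls than the adjusted p threshold aims for. The calls on the real data may therefore hold more false ones than that threshold implies. Among the 4-fold changes for RNA on exons, 40 of those recovered rose and 18 fell.

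The alternatives were median-of-ratios size factors, the DESeq2 Wald test, limma voom, no filter on low counts, a mean of at least 50 counts, the 50 most abundant genes removed, the title's replicate number as a block, the lysate as a block, a log2 fold of at least 1, coding-sequence in place of exon counts, a spread shared by all 8 libraries, the mock libraries alone and each library left out in turn. A mean of at least 500 counts was added after seeing the data. Gene families were also tested after seeing the data, by Fisher's exact test against all tested genes.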

Results

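The data came from leaves of 3-week-old Arabidopsis thaliana plants of the Col-0 ecotype. The leaves were infiltrated with 10 µM elf18, a peptide of bacterial elongation factor Tu that plants sense through the receptor kinase EFR, or with 10 mM MgCl2 as mock. Every plant carried a luciferase transgene behind the leader of TBF1, a heat-shock-factor-like transcription factor whose leader holds upstream open reading frames. From each of 4 lysates, 2 mock and 2 elf18, 1 RNA-seq library and 1 ribosome footprint library were made, which gave 8 libraries in 4 groups of n = 2. Each lysate pooled 2 leaves from each of about 24 plants. The time between infiltration and harvest was not given in the sources used here.

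Counts over coding sequences totalled 12202536 and 6409393 in the mock RNA libraries, 9129108 and 12834781 in the elf18 RNA libraries, 4752563 and 6717946 in the mock footprint libraries and 6202819 and 5272725 in the elf18 footprint libraries. Counts over exons in the same RNA libraries were 15031282, 7898180, 11127372 and 15405467. The elf18 RNA libraries stood apart in the number of genes with at least 1 coding-sequence count, 13791 and 13493 against 16540 and 16767 in mock. The footprint libraries detected 12935 and 17795 genes in mock and 16232 and 13916 with elf18. Replicates correlated across 10969 genes, on log2 CPM, the log2 of counts scaled to library size, at r = 0.935 for mock RNA, 0.707 for elf18 RNA, 0.782 for mock footprints and 0.815 for elf18 footprints.

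**Figure D1:**
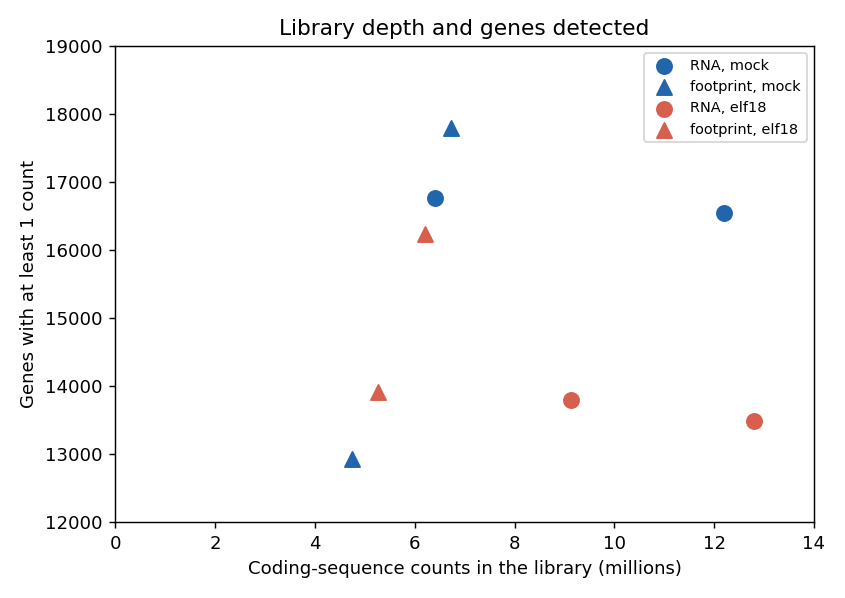
Genes with at least 1 coding-sequence count (vertical axis) against the total coding-sequence count (horizontal axis) for each of the 8 libraries. The elf18 RNA libraries detected 13791 and 13493 genes and the mock RNA libraries 16540 and 16767.

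The transcripts that changed in abundance with elf18 were sought in exon counts of the 4 RNA libraries. Early elicitor-response genes rose: 20 of 25 measured members rose and none fell, with a list median of 2.25 on the log2 scale. WRKY33, a transcription factor of camalexin synthesis, rose 4.75-fold (log2 2.25 ± 0.13, standard error here and below, n = 2 libraries per group, adjusted p = 0.00127). CYP81F2, a cytochrome P450 of indole glucosinolate metabolism, rose 14.9-fold (log2 3.90 ± 0.15), PROPEP3, the precursor of a Pep danger peptide, 24.5-fold (log2 4.62 ± 0.65, 3.97 to 5.07 across settings), and CML37, a calmodulin-like protein, 6.99-fold (log2 2.80 ± 0.23). The NADPH oxidase gene RBOHD rose by 2.02 ± 0.12 on the log2 scale.

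Immune receptors and co-receptors rose at 6 of 18 measured genes and fell at none (list median 1.05). The chitin receptor kinase LYK5 rose 6.23-fold (log2 2.64 ± 0.16), the receptor-like cytoplasmic kinase BIK1 3.31-fold (log2 1.73 ± 0.16) and the co-receptor kinase SOBIR1 2.89-fold (log2 1.53 ± 0.09); PEPR1, BIR1 and BAK1 also rose. EFR itself had a log2 change of 0.16 ± 0.55 (adjusted p = 0.981), with 735 and 307 exon counts in the elf18 libraries and 671 and 314 in mock. The sign of the EFR value rested on which elf18 library was used: it was -0.90 without RNA elf18 replicate 1 and 0.77 without RNA elf18 replicate 2. Each of these fits leaves 1 elf18 library, so the spread within the elf18 group is not measured in it.

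In MAP kinase and calcium-dependent kinase signalling, 6 of 17 measured genes rose and none fell (list median 0.54). The MPK4 substrate MKS1 rose 5.26-fold (log2 2.39 ± 0.20), the kinase MPK11 4.51-fold (log2 2.17 ± 0.20) and the kinase MKK4, which acts above MPK3 and MPK6, 4.08-fold (log2 2.03 ± 0.18). Genes of tryptophan, indole glucosinolate and camalexin synthesis rose at 7 of 18 and fell at none (list median 1.42). Among them IGMT2, an indole glucosinolate methyltransferase, rose 32.6-fold (log2 5.03 ± 0.42, 4.57 to 5.84 across settings), the tryptophan synthase gene TSB1 3.93-fold (log2 1.97 ± 0.14) and the myrosinase gene PEN2 3.41-fold (log2 1.77 ± 0.13).

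Hormone lists moved in part. Of 19 measured genes of salicylic acid synthesis and response, 4 rose and none fell: the transcription factor gene CBP60G by 3.71-fold (log2 1.89 ± 0.16), EDS1 by 2.86-fold (log2 1.51 ± 0.21), the salicylic acid receptor gene NPR3 by 2.02-fold (log2 1.02 ± 0.14), and NPR1 by 0.99 ± 0.15 on the log2 scale. Of 24 jasmonate genes, 5 rose and 1 fell (list median -0.12). The lipoxygenase genes LOX4 and LOX3 rose 3.77-fold and 2.14-fold (standard error 0.09 on the log2 scale for each), and the allene oxide cyclase gene AOC3 2.04-fold (log2 1.03 ± 0.16). CYP94C1, which encodes an oxidase of jasmonoyl-isoleucine, fell by 0.85 ± 0.11 on the log2 scale. In the ethylene list 1 of 17 rose, the ACC synthase gene ACS6 by 2.12-fold (log2 1.08 ± 0.18), with a list median of -0.03.

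Outside these groups single genes rose: BZIP60, a transcription factor of the unfolded protein response, 4.66-fold (log2 2.22 ± 0.12), as the only one of 17 measured endoplasmic reticulum and heat shock genes, and S6K2, a kinase of ribosomal protein S6, 4.08-fold (log2 2.03 ± 0.18), as the only one of 20 translation factors and regulators. No member passed the test among 16 auxin genes (median -0.45), 27 genes with known regulatory upstream open reading frames (-0.27), 22 cytosolic ribosomal proteins (-0.11), 29 nuclear-encoded photosynthesis genes (-0.05), 10 circadian clock genes (-0.22), 7 guard cell markers (0.02), 5 epidermis and trichome markers (-0.18), 7 vascular markers (-0.03) or 10 reference genes (-0.06). TBF1 had a log2 change of 0.23 ± 0.20 (adjusted p = 0.785) on exon counts, which include its leader. On coding-sequence counts its mean RNA level was 62.1 CPM in mock (standard deviation 2.09) and 89.5 CPM with elf18 (0.739). TBF1 was not called on those counts either, where no gene of the upstream reading frame list rose or fell. FRK1, a marker of the elicitor response, was too rare to test, with 0 and 0 exon counts in mock and 17 and 0 with elf18.

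The largest rises belonged to genes near absence in mock. CYP82C3, a cytochrome P450, had 0 counts in mock and 1092 over the elf18 libraries, at least 349-fold higher against a floor of 3 counts over the group. AT4G28460 was 511-fold higher (95% counting interval 141 to 4220) and AT4G22030 460-fold (127 to 3810), each from 2 counts in mock. Their elf18 counts were 771 and 294, and 225 and 735. Across settings their fitted log2 values ran from 7.52 to 12.29 and from 7.17 to 11.94. AT4G04480, AT2G36690, AT4G18540, AT2G31345 and AT2G14290 rose by 8.07 ± 1.01, 7.95 ± 0.60, 7.90 ± 1.05, 6.33 ± 0.81 and 5.76 ± 1.01 on the log2 scale. These 5 values depended on the setting, from 6.71 to 13.24, 7.34 to 10.47, 6.55 to 13.09, 5.67 to 9.42 and 5.09 to 6.71 in the same order. None of these 8 genes, nor PROPEP3, passed under limma voom, where their adjusted p ran from 0.0785 for CYP82C3 to 0.41 for AT4G28460.

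Among genes that fell, the B-box zinc finger genes BBX15 and BBX14 fell to 0.156 and 0.218 of their mock level (standard errors 0.43 and 0.27 on the log2 scale, with BBX15 from -3.28 to -2.25 across settings), and the CONSTANS-like gene COL2 to 0.309 (0.27). The cyclic nucleotide-gated channel gene DND1 fell to 0.36 (0.17), the abscisic acid receptor gene PYL4 to 0.393 (0.13), the phosphomannose isomerase gene MEE31 to 0.35 (0.25), and AT2G38240 and AT5G25280 to 0.287 (0.25) and 0.289 (0.22). The calls of AT2G38240, COL2, MEE31 and ACS6 were lost without either RNA mock library, those of AT2G14290 and AOC3 without RNA mock replicate 1 and that of NPR3 without RNA mock replicate 2, with adjusted p from 0.0551 for ACS6 to 0.389 for MEE31. On coding-sequence counts AT4G28460 (adjusted p = 0.156), AT2G14290 (0.0612), MEE31 (0.0517), AOC3 (0.0957) and ACS6 (0.0742) did not pass.

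Across all 15870 genes tested on exon counts, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 483 risen and 25 fallen, so 95.1% of calls rose; 448 and 13 of these changed at least 2-fold. On coding-sequence counts 400 rose and 18 fell of 15441, of which 396 and 17 were also called on exons. The share of rises depended on the test: DESeq2 called 1245 risen and 1383 fallen (47.4% risen). Leaving out either elf18 RNA library also lowered the share in the edgeR test. Such a fit takes its spread from the mock RNA pair, whose replicates correlated at r = 0.935 against 0.707 for elf18 RNA. Its share of rises is therefore not comparable with that of all 4 libraries. Of the 1383 genes DESeq2 called fallen, 736 had 0 counts in both elf18 libraries and 91 in one. Among 3708 genes with a mean of at least 500 counts, a filter added after seeing the data, 623 rose and 167 fell (78.9%).

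The gene lists were compared with all other genes by camera, a competitive gene set test. With its preset correlation, adjusted p was 2.65e-51 for early elicitor-response genes, 1.7e-15 for tryptophan, indole glucosinolate and camalexin synthesis, 1.72e-11 for immune receptors, 6.88e-10 for kinase signalling and 0.0289 for salicylic acid genes. With an estimated correlation, adjusted p was 0.0882, 0.104, 0.104, 0.104 and 0.367 for the same lists. Adjusted over the list alone, 22 early elicitor-response genes, 12 tryptophan and glucosinolate genes, 10 receptors, 6 kinase genes and 6 salicylic acid genes rose, and 1 salicylic acid gene fell. The salicylic acid list had a median of 0.37 but a mean of -0.28, while camera placed it higher; it lost its call without RNA mock replicate 2 (adjusted p = 0.122), RNA elf18 replicate 1 (0.0563) or RNA elf18 replicate 2 (0.28). Adjusted over the list alone, the jasmonate list had 7 risen and 4 fallen genes and the ethylene list 3 and 1. By fry, which asks whether the members moved together in these samples without reference to other genes, adjusted p was 0.00697, 0.00746, 0.0321, 0.0189 and 0.0492 for the lists in the order given above; fry also gave 0.0492 for the ribosomal proteins, downward.

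Ribosome occupancy with elf18 was compared in the 4 footprint libraries. Of 24 measured early elicitor-response genes, 15 rose and none fell (list median 1.77). WRKY33 rose 4.89-fold (log2 2.29 ± 0.18, adjusted p = 1.68e-05), CYP81F2 13.6-fold (log2 3.76 ± 0.30) and the transcription factor gene WRKY11 6.10-fold (log2 2.61 ± 0.22). PROPEP3 had 0 footprints in mock and 315 with elf18, at least 112-fold higher against the 3-count floor. Receptors rose at 6 of 19 and fell at none (list median 1.09), among them LYK5 by 4.92-fold (standard error 0.25 on the log2 scale), BIK1 by 3.64-fold (log2 1.86 ± 0.32) and the chitin co-receptor gene CERK1 by 2.76-fold (log2 1.47 ± 0.31).

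Kinase signalling genes rose in footprints at 4 of 17 and fell at none (list median 0.79): MKK4 by 8.43-fold (log2 3.08 ± 0.46, 2.56 to 3.93 across settings), MPK11 by 4.50-fold (log2 2.17 ± 0.34), MPK3 by 2.99-fold (log2 1.58 ± 0.15) and the calcium-dependent kinase gene CPK28. Tryptophan, indole glucosinolate and camalexin genes rose at 5 of 17 (list median 1.06), with the glutathione S-transferase gene GSTF6 at 4.33-fold (log2 2.12 ± 0.38), PEN2 at 3.07-fold (log2 1.62 ± 0.12) and GGP1, a peptidase of glutathione conjugates, at 2.79-fold (log2 1.48 ± 0.22). Salicylic acid genes rose at 3 of 18: EDS1 by 3.56-fold (log2 1.83 ± 0.26), CBP60G by 3.53-fold (log2 1.82 ± 0.28) and NPR1 by 2.09-fold (log2 1.07 ± 0.25). In the jasmonate list 4 of 24 rose, with LOX4 at 3.42-fold (log2 1.78 ± 0.12) and AOC3 at 2.29-fold (log2 1.19 ± 0.24), and CYP94C1 fell by 0.99 ± 0.17 on the log2 scale (list median -0.15). In the ethylene list EBF2, an F-box protein that targets EIN3, was the only one of 16 to fall, to 0.407 of its mock level (standard error 0.30 on the log2 scale), and none rose (list median -0.01).

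Footprints of nuclear-encoded photosynthesis genes fell at 6 of 29 members, with 28 of 29 log2 values below 0 and a list median of -0.32. The light-harvesting genes LHCB1.4 and LHCB1.5 fell by 1.02 ± 0.16 and 0.70 ± 0.12 on the log2 scale and the Rubisco small subunit gene RBCS1A by 0.50 ± 0.07; LHCB6, LHCB3 and PSBO1 also fell. BZIP60 rose 3.54-fold (log2 1.82 ± 0.20), alone of 16 in its list (median -0.33), and S6K2 4.93-fold (standard error 0.45 on the log2 scale, 1.86 to 2.96 across settings), alone of 20 (median -0.19). No member passed among 15 auxin genes (median 0.15), 24 genes with upstream open reading frames (-0.03), 22 ribosomal proteins (-0.10), 10 clock genes (-0.12), 7 guard cell markers (-0.63, all below 0, camera adjusted p = 0.2), 5 epidermis and trichome markers (-0.46), 7 vascular markers (-0.07) or 10 reference genes (-0.09). EFR had a footprint log2 change of 0.40 ± 0.32 (adjusted p = 0.988) and TBF1 of 0.33 ± 0.28 (adjusted p = 1).

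The largest footprint rises outside the lists were those of GLR2.9, a glutamate receptor-like channel gene, at 337-fold (95% counting interval 92.8 to 2780) from 2 counts in mock, and of AT4G22030, AT4G18540, DMP1, AT5G11140, AT4G04480 and the wall-associated kinase-like gene WAKL10, at 6.63 ± 1.17, 6.29 ± 0.73, 5.79 ± 0.89, 5.68 ± 0.47, 5.36 ± 0.63 and 5.01 ± 1.05 on the log2 scale. Across settings AT4G22030 ran from 6.28 to 7.22, AT4G18540 from 5.54 to 8.84, DMP1 from 4.91 to 12.26, AT4G04480 from 4.58 to 6.76 and WAKL10 from 4.09 to 11.54. The fitted log2 value of GLR2.9 ran from 7.58 to 11.26. CLPS3, a factor of messenger RNA 3′ end processing, had 317 footprints in mock and 0 with elf18, at least 98.7-fold lower. The CONSTANS-like gene COL1 fell by 2.29 ± 0.39, the ribosomal protein L8 gene EMB2296 by 1.34 ± 0.30, the zinc finger gene ATCTH by 1.29 ± 0.26, PYL4 by 1.22 ± 0.23 and DND1 by 1.15 ± 0.23 on the log2 scale. Under limma voom PROPEP3, GLR2.9, AT4G22030, AT4G18540, DMP1, WAKL10 and CLPS3 did not pass (adjusted p from 0.101 for PROPEP3 to 0.369 for AT4G22030), and DMP1 (0.0823) and WAKL10 (0.172) did not pass under DESeq2.

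Several footprint calls were lost when 1 library was left out, most with a fold close to that of all libraries. With EBF2 left at -1.03 to -1.32 on the log2 scale, DND1 at -1.12 and -1.13, S6K2 at 2.22 and AOC3 at 1.15, adjusted p passed 0.05; the value of NPR1 moved to 0.76, of EMB2296 to -0.93 and of GSTF6 to 1.62. Without footprint mock replicate 1 CLPS3 was lost (adjusted p = 0.106), and EBF2 was lost without footprint mock replicate 2 (0.131), elf18 replicate 1 (0.141) or elf18 replicate 2 (0.178). Without footprint elf18 replicate 1 ATCTH (0.128), DND1 (0.0862), CERK1 (0.18) and S6K2 (0.0852) were lost, and without footprint elf18 replicate 2 EMB2296 (0.227), PYL4 (0.0742), DND1 (0.0573), NPR1 (0.663), AOC3 (0.0917), CYP94C1 (0.0755) and GSTF6 (0.199). With a mean of at least 50 counts required, WAKL10 (0.0646), EMB2296 (0.0881), EBF2 (0.0684) and NPR1 (0.0631) did not pass, and WAKL10 (0.0903) did not pass with a spread shared by all 8 libraries.

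In total 374 genes rose and 24 fell in footprints of 14446 tested by edgeR's quasi-likelihood test, so 94% of calls rose; 338 and 8 changed at least 2-fold. DESeq2 called 651 and 219 (74.8% risen), limma voom 485 and 108 (81.8%), and edgeR called 816 and 184 (81.6%) without footprint mock replicate 2, 289 and 58 (83.3%) without footprint elf18 replicate 1 and 368 and 90 (80.3%) at a mean of at least 500 counts. By camera, adjusted p was 5.87e-47 for early elicitor-response genes, 1.44e-12 for receptors, 7.08e-11 for tryptophan and glucosinolate genes, 3.82e-06 for kinase signalling, 0.0273 for salicylic acid genes, all upward, and 3.04e-07 for photosynthesis genes, downward. With an estimated correlation, adjusted p was 0.0679, 0.2, 0.164, 0.299, 0.318 and 0.176 in the same order. Adjusted over the list alone, 21 early elicitor-response genes, 11 receptors, 9 tryptophan and glucosinolate genes, 5 kinase genes and 6 salicylic acid genes rose, and 13 photosynthesis genes fell; the jasmonate list had 7 risen and 6 fallen genes and the ethylene list 3 and 3. The salicylic acid list had a median of 0.35 and a mean of -0.01, and lost its call without footprint mock replicate 2 (adjusted p = 0.138) or elf18 replicate 2 (0.107). By fry, adjusted p was 0.00207, 0.0514, 0.0183, 0.0567, 0.0514 and 0.0445 in the same order, and 0.0191, downward, for genes with upstream open reading frames.

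**Figure D2:**
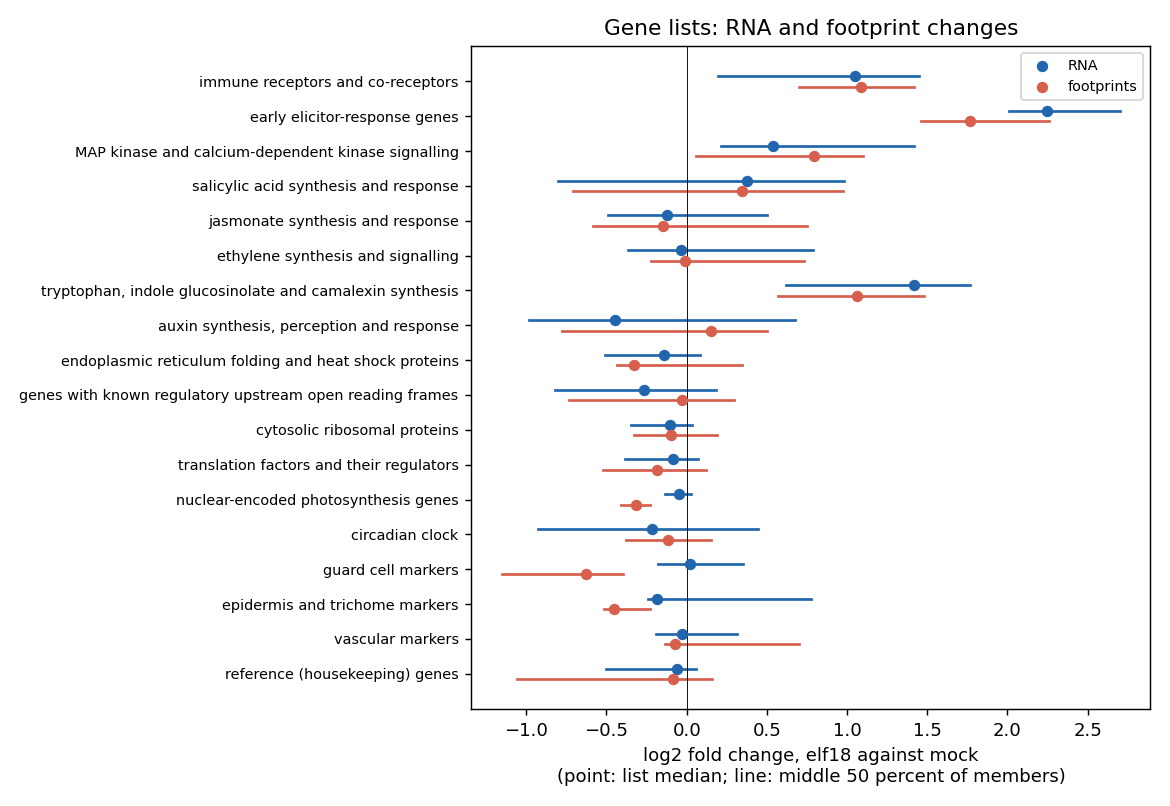
Median log2 fold change, elf18 against mock (horizontal axis), of the members of each of the 18 gene lists, in RNA exon counts and in footprints, with a line over the middle 50 percent of members. The early elicitor-response list had medians of 2.25 in RNA and 1.77 in footprints, and the photosynthesis list -0.05 and -0.32.

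Whether the genes that rose in RNA were those that rose in footprints was tested on coding-sequence counts of 13949 genes tested in both. Of 399 genes risen in RNA and 374 risen in footprints, 297 were shared, against 10.7 by chance (Fisher's exact test, log10 p = -444), among them WRKY33, CYP81F2, LYK5, MPK3, CBP60G, LOX4 and PEN2. Of the 18 and 24 fallen genes, 4 were shared against 0.031 by chance (log10 p = -7.69). These tests treat genes as independent units, and both assays came from the same 4 lysates, so neither p measures the spread between lysates. Footprint values were above 0 for 397 of the 399 genes risen in RNA, and RNA values for 374 of the 374 risen in footprints. Across the 297 shared genes the median log2 change was 1.99 in RNA and 1.82 in footprints, with the footprint change the smaller at 190. Across all 13949 genes the correlation of the changes was r = 0.202 (Spearman 0.227), and it was 0.399 (Spearman 0.301) across 10936 genes with a mean of at least 50 counts. Changes from the libraries numbered 1 and those numbered 2 correlated at only 0.234 within RNA and 0.0577 within footprints. At a mean of at least 50 counts these values were 0.25 and 0.124. Noise therefore limits r, which does not measure how closely footprints follow RNA.

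**Figure D3:**
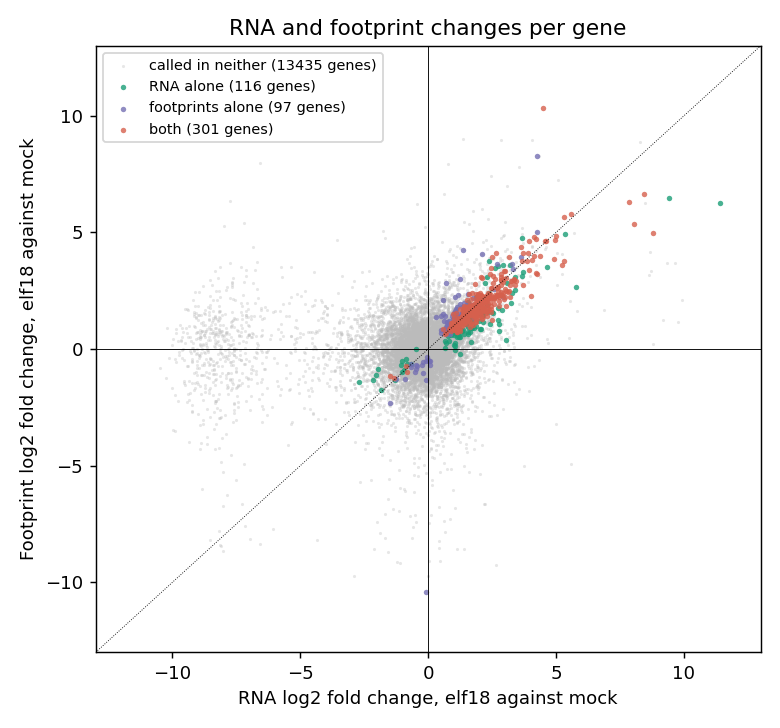
Footprint log2 fold change (vertical axis) against RNA log2 fold change (horizontal axis), elf18 against mock, for 13949 genes tested in both on coding-sequence counts, with genes called in RNA, in footprints or in both marked. The correlation across all genes was r = 0.202. Changes of single replicates correlated at 0.234 within RNA and 0.0577 within footprints.

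Whether translational efficiency changed, that is whether footprints changed beyond RNA, was asked of all 8 coding-sequence libraries through the interaction of assay and treatment. Nuclear-encoded photosynthesis genes were the only list past camera: 26 of 29 members had a value below 0, with a median of -0.20 (adjusted p = 3.49e-06; adjusted p = 0.482 with an estimated correlation; fry adjusted p = 0.267). No member was called over all genes, and 4 fell adjusted over the list alone. The list median lay at percentile 5.86 of 10000 random lists matched on abundance, whose median was -0.13. With the lysate as a block, 3 members fell (LHCB1.4, LHCB1.5 and RBCS1A), with camera adjusted p = 8.96e-07 and adjusted p = 0.731 with an estimated correlation. The median log2 ratio of footprints to RNA in the list was -0.85 and -0.91 in the mock lysates and -1.02 and -1.09 in the elf18 lysates, while across genes of at least 10 CPM it was -0.02, 0.03, 0.07 and 0.07.

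**Figure D4:**
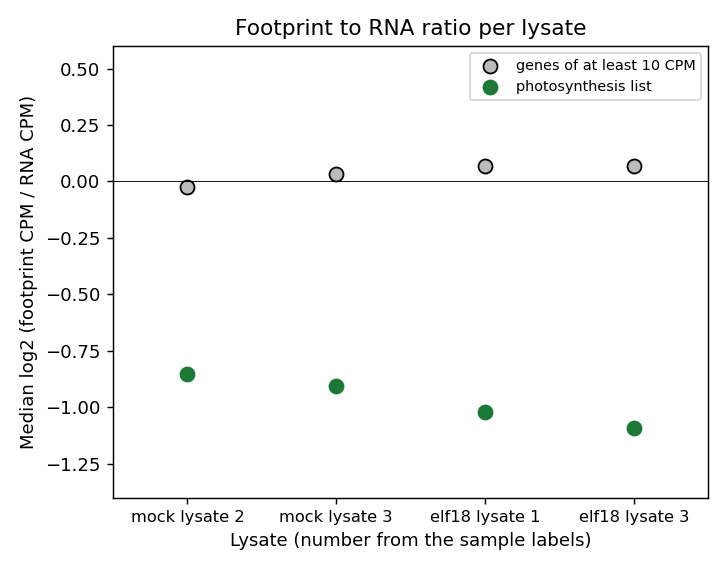
Median log2 ratio of footprint to RNA CPM (vertical axis) in each of the 4 lysates (horizontal axis), for the photosynthesis list and for genes of at least 10 CPM. The photosynthesis list had medians of -0.85 and -0.91 in mock and -1.02 and -1.09 with elf18.

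Other groups had efficiency medians near 0 and no called member: 0.09 for receptors, -0.08 for early elicitor-response genes (fry adjusted p = 0.0488, downward, and 0.516 with the lysate as a block), -0.18 for kinase signalling, 0.02 for salicylic acid, -0.03 for jasmonate, -0.04 for ethylene, -0.14 for tryptophan and glucosinolate genes, 0.10 for auxin, 0.12 for endoplasmic reticulum and heat shock genes, 0.04 for ribosomal proteins, 0.07 for translation factors, 0.14 for clock genes, 0.17 for vascular markers, -0.13 for epidermis markers and 0.03 for reference genes. The 7 guard cell markers had a median of -0.63. The early elicitor-response and kinase lists passed camera, downward, without footprint elf18 replicate 2 (medians -0.18 and -0.30, adjusted p = 0.0399 each). The 27 genes with known regulatory upstream open reading frames had a median of -0.08, with 13 above 0. TBF1 had an efficiency change of -0.17 ± 0.38 (adjusted p = 1), EFR of 0.33 ± 0.60 (adjusted p = 1) and WRKY33 of 0.06 ± 0.24 (adjusted p = 1).

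No gene changed in efficiency by edgeR's quasi-likelihood test, 0 up and 0 down of 16177, and 725 had an unadjusted p under 0.05. With the lysate as a block the same test called 1 up, AT1G72645, and 5 down, AT2G36690, IGMT2, LHCB1.4, LHCB1.5 and RBCS1A. AT1G72645 had 150 and 125 RNA counts in mock and 1 and 101 with elf18, so its rise leans on RNA elf18 replicate 1. DESeq2 called 38 up and 32 down, 26 of these 70 with a group at 0 counts, and limma voom called 2 up, the myrosinase gene TGG1 and AT2G45180. On simulated counts of these genes the test recovered 24 of 100 4-fold and 3 of 100 2-fold efficiency changes, so an absence of calls leaves changes of these sizes open.

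The genes with the largest test statistics, given as values and not as calls, included AT2G36690 (log2 -3.80 ± 0.64, adjusted p = 0.299), LHCB1.5 (-0.75 ± 0.15, adjusted p = 0.893) and the peroxidase gene PER4 (-1.02 ± 0.22, adjusted p = 1) on the lower side. On the higher side was AT1G45000 (2.31 ± 0.59, adjusted p = 1). HESO1, which uridylates small RNAs, NdhT, a subunit of the chloroplast NDH complex, and AT5G44250 had 0 RNA counts in both elf18 libraries, which gave ratios of footprints to RNA at least 96.7-fold, 82.9-fold and 65.1-fold higher (adjusted p = 1 each). These bounds rest on zeros in the elf18 RNA libraries, which detected fewer genes. CLPS3, with no elf18 footprints, had a ratio at least 84.5-fold lower (adjusted p = 1). DESeq2 passed all 8 of these genes, with adjusted p from 0.000101 for AT2G36690 to 0.0129 for AT1G45000. AT2G36690 also passed without RNA mock replicate 1 (log2 -5.27, adjusted p = 0.0159) and LHCB1.5 at a mean of at least 500 counts (adjusted p = 0.0427).

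How footprints stood to RNA in unstimulated leaves was asked of the mock contrast of the same fit, relative to the average gene. Photosynthesis genes lay lowest: 23 of 29 members were below the average ratio and none above, with a list median of -0.90. LHCB1.3, LHCB1.5 and RBCS1A had log2 ratios of -2.32 ± 0.12, -1.95 ± 0.11 and -1.12 ± 0.10. These belong to the 19 members outside the single-copy set, whose median was -1.39. The 10 single-copy members had a median of -0.70, so the size of the low ratio differed with gene copies. Cytosolic ribosomal protein genes were below at 5 of 22 (median -0.78), with RPL23AA at -1.51 ± 0.25 and RPS13A at -1.44 ± 0.25. Receptor genes were above at 3 of 19 (median 0.35): LYK5 at 0.91 ± 0.22, the receptor kinase gene FER at 0.70 ± 0.17 and SOBIR1 at 0.67 ± 0.13. The target of rapamycin kinase gene TOR (1.28 ± 0.23), the elongation factor 2 gene LOS1 (0.75 ± 0.14), RBOHD (0.87 ± 0.14), the jasmonate transcription factor gene MYC2 (0.89 ± 0.18) and the transporter gene PEN3 (0.84 ± 0.09) were also above. PROPEP3, with 0 footprints in mock, and GSTF6 (-1.56 ± 0.31), from the lists that hold RBOHD and PEN3, were below. Members of this paragraph's lists were picked for naming after their values were seen. Gene length was not checked, so whether the ratios vary with it was not tested.

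Across 16177 genes, 252 were above and 302 below the average ratio, and 392 and 501 with the lysate as a block. By camera, adjusted p was 4.45e-56 for photosynthesis genes, 0.000308 for ribosomal proteins and 0.0436 for receptors. With an estimated correlation, adjusted p was 0.0355, 0.0936 and 0.453; with the lysate block it was 0.557, 0.557 and 0.579. Adjusted over the list alone, 27 photosynthesis and 9 ribosomal protein genes were below, and 3 receptor genes were above and 1 below. The 27 genes with upstream open reading frames had a median of -0.01, with ARF2, an auxin response factor, above (0.62 ± 0.16) and none below.

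The labels do not say whether the lysates came from independent plantings, so p-values here measure the spread between these samples. Strand setting and the treatment of reads that match several genes were not given in the sources used here, so values of near-identical copies (LHCB1, LHCB2, RBCS, EDS1, IGMT1 and IGMT2, TSB1, the AOC genes and GSTF6) and of overlapping genes are less certain than the rest. Intervals and floors cover counting error only.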

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

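One result met a rule set before the data were examined, that the effect of elf18 differs between the 2 assays: footprints of nuclear-encoded photosynthesis genes fell relative to their RNA, with a median difference of -0.199 on the log2 scale and a camera adjusted p of 3.49e-06 at the preset correlation. With an estimated correlation the adjusted p was 0.482, and no single member was called over all genes.

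For this photosynthesis pattern the test that left out each library was chosen only after the result was seen; the others were written before. Reads shared between near-identical gene copies could not be the whole cause of values below 0. The 10 single-copy members had a median efficiency change of -0.198 (95% bootstrap interval over genes -0.34 to -0.0425), with 9 below 0, which met the limit set beforehand. That interval also holds -0.129, the median of the abundance-matched random lists below. Whether shared reads add to a fall beyond that of abundant genes was therefore left undecided. A single library that stands apart could not be the whole cause of a median below 0. The list median stayed between -0.317 and -0.177 without any one of the 8 libraries. Abundance-matched lists were not drawn for these fits. Whether 1 library made the list fall beyond abundant genes was therefore left undecided. A shift of all abundant genes remained possible: the list median lay at percentile 5.86 of 10000 abundance-matched random lists, within the middle 95 percent, which ran from -0.241 to -0.0793. The values therefore do not separate a change in the translation of these genes from a shift that abundant genes share.

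Fewer genes were detected in the elf18 RNA libraries than in the mock RNA libraries, and here the tests by thinning and on summed footprints were chosen only after the result was seen. Lower depth was excluded: with every RNA library thinned to 6407027 counts, the gap between mock and elf18 was still at least 2770 genes. A loss from the cells was left undecided for the 757 genes at 0 counts in both elf18 RNA libraries and with a mean of at least 20 counts in mock RNA: the 472 tested in footprints had a median log2 change of 0.0419 (95% bootstrap interval -0.125 to 0.226), above the limit set beforehand, but the footprint filter that chose them depends on the change itself, and the 285 others went from 332 to 178 CPM in sum. With no such filter the summed footprints of all 757 went from 2900 to 2260 CPM (log2 -0.361, 95% bootstrap interval -0.485 to -0.239), below lists matched on mock RNA counts and detected in both elf18 RNA libraries (median 0.379, middle 95 percent 0.219 to 0.549), and 26 of the genes had at least 20 footprints in mock and 0 with elf18, against 0 the other way. A separate loss of transcripts in each library was left undecided: among genes with a mean of at least 50 counts in mock RNA, those at 0 in one elf18 library (573 and 739 genes, 174 of them at 0 in both) had a median of -0.94 against mock in the other (95% bootstrap interval -1.13 to -0.799), within the 2-fold limit set beforehand but with an interval that crosses it, and joint zeros exceeded independence at a mock mean of 50 to 100 counts (154 against 97.1) and 100 to 200 (20 against 6.33), so what the elf18 RNA libraries share remains open.

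Changes in efficiency and in RNA correlated negatively across genes, at a mean r of -0.643 within the same libraries; the test of this pattern was chosen only after the result was seen. RNA measurement error that both values share could account for it, since between libraries that share none the mean r was -0.062. The individual correlations were -0.616 and -0.669 within and -0.103 and -0.0211 between. Between the libraries numbered 1 and those numbered 2, efficiency changes correlated at r = 0.00517 and RNA changes at 0.234. With so little agreement a true relation could hardly show between libraries, so whether one exists beside shared error was left undecided.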

How the results depend on the processing

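With 2 libraries per group, depth and spread limited what could be called, and a left-out library leaves a group with 1 library that is assumed to vary like the others. All 483 risen and 25 fallen genes of RNA exon counts kept their call under DESeq2, median-of-ratios size factors, no filter and a mean of at least 50 counts; limma voom kept 436 and 24, and without RNA mock replicate 1 or 2 the calls kept were 413 and 11 or 406 and 13. Median-of-ratios size factors and removal of the 50 most abundant genes kept the counts of calls for RNA, footprints and efficiency within 1.5 times; neither was run for the ratio in mock or for the lists. Nuclear genes alone were not run as a separate setting, since the tables held no plastid or mitochondrial genes, so it would equal the main analysis. The cause of each change below was not tested unless stated.

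On exon counts, DESeq2 called 1245 risen and 1383 fallen. The fallen count was 63 with limma voom, 47 with no filter, 38 at a mean of at least 50 counts, 13 with a log2 fold of at least 1 as well, by construction, and 167 at a mean of at least 500 counts, which was added after seeing the data and tests fewer genes. Without 1 library the risen count ran from 451 to 1692 and the fallen count from 14 to 3247. On coding-sequence counts, DESeq2 called 1162 risen and 1463 fallen. The fallen count was 77 with limma voom, 30 with no filter, 32 at a mean of at least 50 counts, 11 with the fold limit, 133 at a mean of at least 500 and 62 with a spread shared by all 8 libraries. Without 1 library the counts ran from 273 to 1401 risen and from 1 to 2914 fallen.

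In footprints, DESeq2 called 651 risen and 219 fallen, and gave no adjusted p for 6442 genes. The fallen count was 108 with limma voom, 96 with no filter, 8 with the fold limit, 90 at a mean of at least 500 and 43 with the shared spread. Without 1 library the counts ran from 289 to 816 risen and from 9 to 184 fallen.

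For efficiency, DESeq2 called 38 up and 32 down and gave no adjusted p for 3450 genes, limma voom 2 up and 0 down, no filter 1 up and 7 down, and a mean of at least 500 counts 0 up and 1 down. Without 1 library the counts ran from 0 to 3 up and from 0 to 1 down. The lysate block gave 1 up and 5 down for efficiency and 392 above and 501 below for the ratio in mock, where the mock libraries alone gave 271 and 293. It ended no call of a list with the preset correlation, and for photosynthesis genes in mock it ended the call with an estimated correlation. The lysate block leaves fewer residual degrees of freedom, which lowers what that setting can call.

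The labels do not say that the replicate number of the titles pairs mock with elf18, and it was not taken to. As a replicate block it moved the calls to 747 risen and 169 fallen on exons, 677 and 159 on coding sequences, 570 and 108 in footprints and 0 and 1 for efficiency (AT2G36690, adjusted p = 0.0182); the salicylic acid list did not pass camera in RNA under this block (adjusted p = 0.0781). Deviations of libraries with the same number correlated at 0.0067 between mock and elf18 RNA and -0.0652 between mock and elf18 footprints.

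Lists past camera fell from 5 in RNA, 6 in footprints and 1 in efficiency to 0, 0 and 0 with an estimated correlation. In RNA the estimate was -0.0399, -0.0338 and -0.0214 for the tryptophan, kinase and salicylic acid lists, below the preset 0.01. It was 0.0182 for early elicitor-response genes and 0.0211 for receptors. A higher correlation does not explain the lost calls of the lists below the preset, and the few residual degrees of freedom also limit this setting. Without 1 library the efficiency comparison had 1 to 3 such lists. The correlation of RNA and footprint changes was 0.399 at a mean of at least 50 counts in place of 0.202. Across the named genes and leave-one-out fits only EFR reversed in RNA, over a range of -0.90 to 0.77; 378 fits kept their side of the threshold, genes without a call included, with the same direction or, for a gene without a call, a shift under 1 standard error. A call was lost in 26 and gained in 2 besides the reversed EFR fit, which also gained one. In 1 more fit an uncalled value, the efficiency of WRKY33, changed sign to -0.23 without footprint mock replicate 1. Under limma voom 75 named genes kept their side of the threshold and 16 lost it, under DESeq2 81 kept it, 8 gained and 2 lost it, and on coding-sequence counts 35 kept it and 5 lost it.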

Other observations

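Gene families were chosen and examined after the data were seen, by name, with 29 families in RNA and 28 in footprints and Fisher's exact tests adjusted over them. The calls tested were those in view when the families were chosen. The p-values therefore describe these calls and are not independent support. WRKY transcription factors rose at 11 of 38 members in RNA, against 1.16 expected (adjusted p = 3.07e-07), and at 8 of 34 in footprints (adjusted p = 3.03e-05). WRKY40, WRKY22, WRKY53, WRKY30 and WRKY48 rose in both assays. The ZAT zinc finger genes ZAT6, ZAT10, ZAT11 and ZAT12 rose in both assays, 4 of 5 members (adjusted p = 6e-05 in RNA and 3.03e-05 in footprints). Autoinhibited calcium ATPases rose at 4 of 8 members in both (adjusted p = 0.00039 and 0.000266), among them ACA1, ACA2 and ACA11. ERF transcription factors rose at 6 of 19 in RNA (adjusted p = 0.000144) and at 2 of 17 in footprints (adjusted p = 0.152). The powdery mildew susceptibility genes MLO2, MLO6 and MLO12 rose in both, 3 of 9 members (adjusted p = 0.0085 and 0.00719), and the exocyst genes EXO70B1, EXO70B2 and EXO70H7 did so as 3 of 13 (adjusted p = 0.0206 and 0.0162).

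Among falling genes, the BBX and CONSTANS-like family had 3 of 21 members in RNA, BBX14, BBX15 and COL2, against 0.0331 expected (adjusted p = 0.000131), while BBX32 rose. The 3 fallen members are among the falling genes already named above, so this p adds no support. In footprints COL1 was the only fallen member of 18 in this family (adjusted p = 0.413). Calcium-dependent kinases rose at 5 of 21 members in RNA (adjusted p = 0.00202), CPK1, CPK5, CPK9, CPK28 and CPK32. Of 50 genes whose symbol begins with RPL or RPS, none passed the test in RNA and RPS6 alone passed in footprints, where it rose; the ribosomal protein L8 gene EMB2296, which fell in footprints, is not among them by name.

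TBF1 stood out in where its RNA counts lay. Of its exon counts 38.4% and 44.5% fell in the coding sequence in mock and 46.4% and 59% with elf18. Over the RNA libraries this share was 47.1%, at percentile 3.07 of 9888 genes with at least 400 exon counts, whose median was 87.3%. The transgene of all samples carries the leader of TBF1, and whether its transcript adds to the exon counts could not be tested with these tables.

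In mock, genes with the highest ratio of footprints to RNA among those with over 3 counts in every mock library, chosen after the values were seen, included AT1G72645 (log2 4.54 ± 0.67), the ubiquitin ligase gene UPL1 (2.09 ± 0.26) and DCAF1 (2.05 ± 0.45). The lowest included AGP12, an arabinogalactan peptide gene (-3.31 ± 0.60), RTFL17 (-3.09 ± 0.54), the outer envelope protein gene OEP6 (-2.98 ± 0.45) and RBCS2B (-2.68 ± 0.25). Whether these extremes vary with gene length was not tested.

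Among genes with a mean of at least 50 counts in the other treatment, the share at 0 counts was 1.11% and 0.937% in the mock RNA libraries, 4.93% and 6.36% in the elf18 RNA libraries, 4.27% and 0.0835% in the mock footprint libraries and 0.274% and 2.38% in the elf18 footprint libraries.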
